A study of Mus musculus with 4 samples.

How the data were processed

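Kidney cells of chimeric mouse embryos were sorted by green fluorescent protein (GFP) and profiled on 4 Affymetrix mouse whole-genome expression arrays, 2 of GFP-positive cells labelled as lacking the transferrin receptor gene Tfrc and 2 of GFP-negative wildtype cells. Per the labels' protocols, kidneys taken on embryonic day 15.5 were digested with collagenase and trypsin before sorting, and 50 ng of total RNA was amplified and biotin-labelled by an isothermal linear method. The values are probe set intensities on a linear scale, as deposited by the authors, and RMA is the only processing tool named in the submitters' processing notes. Its version and settings, and the step that returned its log2 output to a linear scale, were not given in the sources used here. RMA adjusts background and equalises the distributions of the arrays, so a difference shared by most genes of an array would be removed from the deposited values. The median intensity was 17.9 and 19.3 on the wildtype arrays and 17.5 and 18.8 on the arrays labelled Tfrc-null.

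The intensities of 45101 probe sets were taken to log2 with no further normalization. The platform annotation gave 1 gene symbol for 34958 probe sets, several for 932, and none for 9211. Symbols were looked up by Entrez identifier in a RefSeq gene table of assembly GRCm38.p6, which held 18033 of the 18194 genes tested. A gene was represented by its probe set with the highest mean log2 value over the 4 arrays, and 9012 genes had more than 1 probe set. Probe sets with several genes or none were left out of the gene-level test. Values that exist only for near-identical copies, such as globin and stefin genes, are uncertain because probes of one copy can bind the other. The control level of an array was the highest of its 27 Bacillus subtilis control probe sets, 7.18 and 9.08 on the wildtype arrays and 7.40 and 7.77 on the others. Where both arrays of a group lay at or below it, a fold is given as a lower bound against that level, and no fold is given where the arrays of the other group did not all lie above it.

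Differences are mean log2 of the arrays labelled Tfrc-null minus mean log2 of the wildtype arrays. They were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, no filter and no block), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 on the adjusted p. Standard errors are those of this model, folds are 2 to the power of the absolute log2 difference, and group values are mean intensity ± SD. A second description with no test counted genes with at least a 2-fold difference and both arrays of one group above both of the other. With 2 arrays against 2, an exact permutation test cannot go below a two-sided p of 0.333. The labels call the arrays biological replicates and do not say which animals they came from, so p-values of single genes measure the spread between these samples. A total of 26 gene lists covering iron handling, stress, cell types of the kidney and its neighbours, imprinted genes and sex-linked genes were fixed before the data were examined. Each was tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 26 lists, and members were also adjusted over each list alone. At this preset a list's p measures the spread across genes, which are not independent replicates, and not the spread between samples.

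The genes named in the text follow a rule fixed before the data were examined. It takes Tfrc with every probe set, every measured member of the iron uptake list, and up to 12 genes per direction. Those were to be the genes past the threshold with the largest differences and no overlap of the groups, and, where fewer than 12 passed, the genes with the largest moderated t and no overlap, named as not past the threshold. It also takes up to 4 members of every other list with the smallest p. Any other gene named was chosen after its values were seen.

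The scripts were tested on simulated data in which 18194 genes had the means and the replicate-number effects of the real arrays. Their variances were drawn from limma's fitted prior with the replicate number as a block. Of genes changed by 1, 2 and 3 on the log2 scale, the fit without a block called 0%, 13.7% and 76.8% over 10 simulations, with 6 false calls in all. With the replicate number as a block it called 0.448%, 76.7% and 94.5%, with 88 false calls. Since a replicate-number effect was put into the simulated data, this gain was built in and does not show that the block suits the real arrays. With no change, 0 of 260 list tests were called. Residuals were drawn independently for each gene, so this could not show false calls from list members that vary together. With the ureteric bud list moved by 0.5 on the log2 scale, camera called it in 10 of 10 simulations at the preset correlation and in 0 of 10 with the correlation estimated from the arrays.

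Alternatives fixed before the data were examined were the replicate number as a block, leaving out each array in turn, a filter at the median level of all probe sets (18.2), the mean of all probe sets of a gene, an intensity trend in the variance prior, quantile normalization, centring each array on its median, every probe set tested on its own, adjusted p thresholds of 0.10 and 0.01, camera with an estimated correlation or on ranks, limma's fry, and lists limited to members at or above the median level. Combinations of the block with the filter, with the trend and with the estimated correlation were added after seeing the data. Where an array was left out, the lone array of its group was assumed to vary like the other group.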

Results

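Gene expression was measured in cells sorted from chimeric mouse kidneys on embryonic day 15.5. Blastocysts of wildtype mice had received 3 to 5 embryonic stem cells that carried GFP and a deletion of Tfrc, which encodes transferrin receptor 1, the main route of iron uptake from transferrin. The kidneys that formed were mixtures of donor and host cells, and sorting by GFP parted them. Each group was profiled on 2 Affymetrix arrays holding 45101 probe sets, so the comparison sets GFP-positive cells labelled Tfrc-null against GFP-negative wildtype cells of chimeric kidneys. The series title states its purpose as gene expression that depends on the transferrin receptor. None of the arrays holds donor-derived cells with Tfrc intact. A difference between the groups can therefore come from Tfrc or from any other difference between donor line and host, and these cannot be told apart.

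The Tfrc signal was not lower in the arrays labelled Tfrc-null. The brightest of its 6 probe sets read 1759 and 2348 on the wildtype arrays and 2509 and 3175 on the arrays labelled Tfrc-null, means of 2053 ± 416.5 and 2842 ± 470.9 (SD, n = 2 each). The log2 difference was 0.47 (SE 0.24, limma adjusted p = 0.744). Of the other probe sets, 4 above the control level also had higher means in the arrays labelled Tfrc-null, by 0.47 to 1.42 on the log2 scale. The one at the 5' end of the transcript lay at or below the control level on all 4 arrays. Which part of the gene was deleted is not given in the sources used here, and a probe set outside that part does not check the label. The group is therefore called "labelled Tfrc-null" throughout, and every direction given rests on that label.

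The genes that stood furthest apart by moderated t included Scara5, a ferritin receptor, with 25.6 ± 8.40 on wildtype and 184.2 ± 51.5 on labelled Tfrc-null arrays, and Hoxd13, a homeobox gene of posterior structures, with 8.32 ± 1.12 and 66.97 ± 8.71 (SD, n = 2). The stefin genes Stfa3 and Stfa2l1, which encode cysteine protease inhibitors of myeloid cells, stood at 816.8 ± 290.5 and 1328 ± 672.1 on wildtype arrays against 7.18 ± 2.38 and 13.1 ± 4.83. Ret, the receptor that drives branching of the ureteric bud, stood at 923.1 ± 188.9 against 84.7 ± 27.8, an 11.1-fold lower level. None of these passed the threshold over all 18194 genes: the adjusted p was 0.0856 for Stfa3 and 0.122 for the other 4. Among the other genes higher on the labelled Tfrc-null arrays were Tmem87a, Ifi202b, Itga9, Polr3gl, Ifi44l, Nrk, Col25a1, Ralyl, Ccn3 and Ttc5, with log2 differences from 1.55 (Ttc5) to 2.92 (Tmem87a). Ifi44l lay at or below the control level on both wildtype arrays, which leaves a fold of at least 2.13. Among those lower were LOC102631979, Ctr9, Mal2, Mir1931, Krt23, Ehf, Olfm4, Aqp4 and Tesc, with log2 differences from -3.20 (LOC102631979) to -1.82 (Tesc). The difference was not shared by all probe sets of a gene. Of 8 further probe sets at or above the median level, in 6 of these 24 genes, 4 differed by under 50% of the difference used or the other way, and the 4 of Nrk, Ccn3 and Ehf stood at 77.9% to 107% of it. A second Ctr9 probe set differed by 0.13, against -2.14 for the one used, 2 further Itga9 probe sets by 0.52 and 0.78, against 2.46, and 1 of Tesc by -0.75, against -1.82.

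With limma, 0 of 18194 genes passed an adjusted p of 0.05, and 1459 genes (8.02%) had an unadjusted p under 0.05 where chance alone gives 909.7. This number was 751 without labelled Tfrc-null replicate 1 and 797 without labelled Tfrc-null replicate 2, both under the chance count, and 1251 and 1913 without wildtype replicate 1 and 2. At least a 2-fold difference without overlap of the groups was seen for 484 genes, 209 higher and 275 lower on the labelled Tfrc-null arrays. With no size of difference required, chance separates 2 values from 2 in 33.3% of genes. That share is for separation alone and cannot be set against the number of 484. This number was 919 without wildtype replicate 2 and 309 with the mean of all probe sets per gene. Array replicates of a group differed about as much as arrays of different groups: the median absolute log2 difference was 0.28 between the wildtype arrays and 0.24 between the labelled Tfrc-null arrays, and 0.20 to 0.30 across groups. Pearson correlations of log2 values across probe sets, which are not independent replicates, were 0.982 and 0.987 within groups and 0.977 to 0.986 across groups. Hybridization and RNA-quality controls split the arrays by replicate number and not by group. A bacterial BioB control read 5350 and 5780 on the 2 arrays numbered 1 and 3760 and 4068 on the 2 numbered 2. The ratio of 3' to 5' beta-actin signal was 5.51 and 5.89 against 6.49 and 7.21. With the replicate number as a block, 2 genes passed, Stfa3 and Stfa2l1. Their log2 differences within replicate 1 and within replicate 2 were -6.80 and -6.85 for Stfa3 and -6.46 and -6.77 for Stfa2l1.

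**Figure D1:**
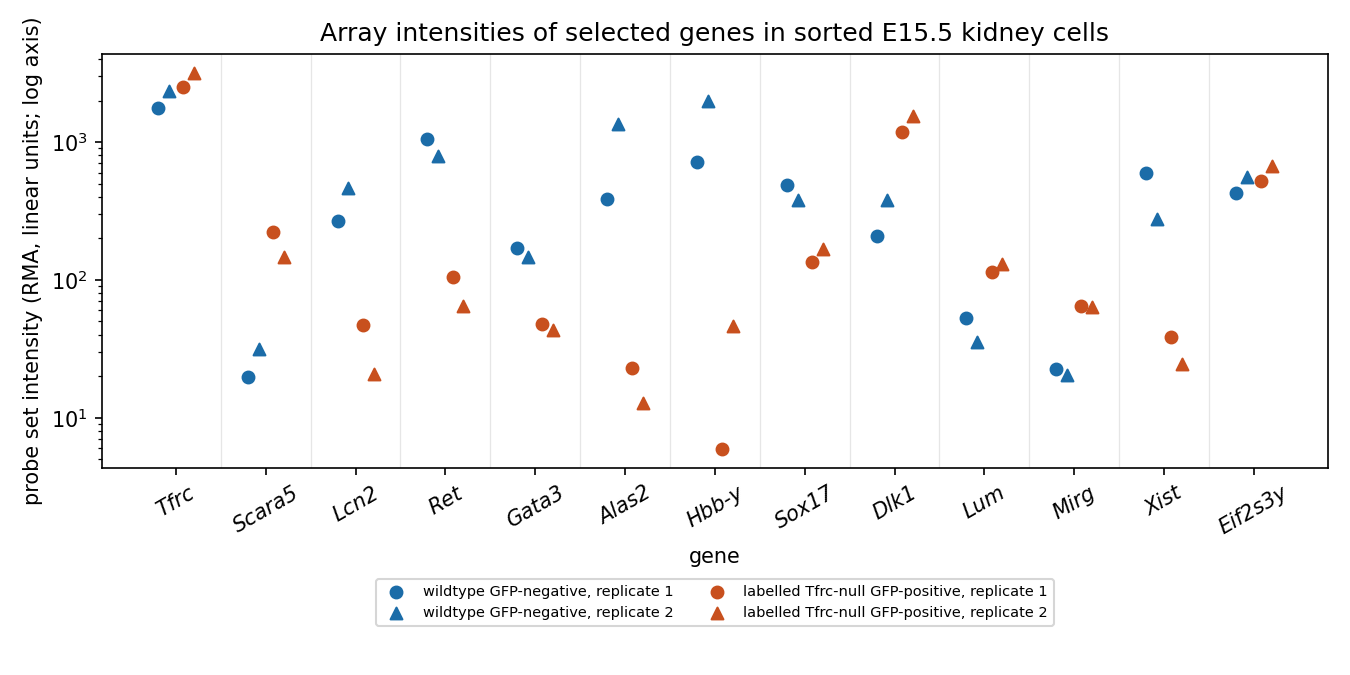
Intensity of 13 genes on each of the 4 arrays, on a log axis, with wildtype arrays in blue and labelled Tfrc-null arrays in orange, circles for replicate 1 and triangles for replicate 2. Tfrc lies between 1759 and 3175 on all arrays, Ret and Lcn2 lie lower on both orange arrays, and Scara5 and Dlk1 lie higher on both.

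Genes of iron uptake did not move as a group, and 2 of them stood far apart in opposite directions. Scara5 was 7.25-fold higher on the labelled Tfrc-null arrays (log2 difference 2.86, SE 0.33, adjusted p = 0.122). Its difference was 3.49 within replicate 1 and 2.23 within replicate 2, and its second probe set lay at or below the control level on all 4 arrays. Lcn2, which encodes the siderophore-binding protein lipocalin 2 and is also made by granulocytes and collecting duct, was 11.3-fold lower, at 33.9 ± 18.3 against 367.2 ± 140.5 (log2 difference -3.50, SE 0.47, adjusted p = 0.148). Of the 16 members measured, 0 passed over all genes, and these 2 passed when adjusted over the list alone. Steap3, an endosomal ferrireductase, stood at 29.3 ± 2.09 against 18.8 ± 2.75, and the importer Slc11a2 at 75.4 ± 28.9 against 51.9 ± 24.9. Log2 differences of other members were -0.44 for Cubn, -0.33 for Slc39a14, -0.18 for Lrp2, -0.12 for Slc22a17, -0.08 for Hfe, 0.01 for Mcoln1, 0.04 for Slc39a8, 0.11 for Tfr2 and 0.28 for Cybrd1. Havcr1 lay at or below the control level on 4 arrays and Timd2 on 3, so no difference is given for them. The list had a median difference of 0.02 and a camera adjusted p of 0.969.

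In haem synthesis and transport, the erythroid first enzyme Alas2 stood at 17.9 ± 7.12 on labelled Tfrc-null arrays against 867.6 ± 680.9 on wildtype arrays, and the mitochondrial transporter Abcb10 had a log2 difference of -2.04 (SE 0.40). Alad, the second enzyme of the pathway, stood at 823.4 ± 4.98 against 370.1 ± 96.2, and the biliverdin reductase Blvrb had a log2 difference of 0.69 (SE 0.20). Of 17 members, 0 passed over all genes, and Alas2, Abcb10 and Alad passed when adjusted over the list alone. The list's median (0.19) and mean (-0.44) differed in sign, its test direction was down and its camera adjusted p was 0.485. The median was -0.10 without wildtype replicate 1 (adjusted p = 0.0619) and 0.03 without wildtype replicate 2 (0.826). For iron storage, export and regulation, 0 of 19 members passed either way (camera adjusted p = 0.443). Bmp6, an inducer of hepcidin, stood at 72.6 ± 1.71 against 43.95 ± 1.88, Hmox1 at 277.5 ± 20.5 against 195.6 ± 5.79 and Tmprss6 at 12.1 ± 1.11 against 8.75 ± 0.761, and Cp had a log2 difference of 1.13 (SE 0.46). Iron-sulphur cluster assembly had 14 of 20 members higher and a median of 0.21 with camera adjusted p = 0.0535, and the 4 members with the smallest p, Hscb, Nubp2, Nfs1 and Iscu, had log2 differences of 0.48 to 0.59. This list passed without wildtype replicate 2 (adjusted p = 0.0402) and without labelled Tfrc-null replicate 2 (0.041), and had a median of 0.10 without wildtype replicate 1 (0.378). Of the iron-containing respiratory chain, 13 of 19 members were higher (median 0.13, camera adjusted p = 0.351), among them Sdhb, Cox6c, Cox5b and Ndufv1 at 0.30 to 0.43, and the median was 0.03 without wildtype replicate 1 (adjusted p = 0.832). Adjusted over either list alone, 0 members passed.

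Genes of the ureteric bud and collecting duct, the branching epithelium that forms the drainage of the kidney, were lower as a group in the cells labelled Tfrc-null. Of 25 members measured, 24 had a lower mean and 17 lay lower without overlap, with a median log2 difference of -0.73 (camera adjusted p = 3.0e-16). The call was lost with an estimated correlation (adjusted p = 0.436). Ret was 11.1-fold lower and Gata3, a transcription factor of the bud, 3.48-fold lower, at 45.4 ± 3.20 against 158.2 ± 17.2. Elf5 stood at 10.8 ± 2.92 against 37.99 ± 1.63. Over all genes 0 members passed, and 9 passed when adjusted over the list alone, all lower: Ret, Lcn2, Gata3, Elf5, and Wnt9b, Calb1, Cdh1, Upk3a and Rhcg, the last 5 named after their values were seen. The list's median was -0.84 within replicate 1 and -0.67 within replicate 2. Genes of the loop of Henle and distal tubule were lower in 15 of 18 members, with a median of -0.22 (camera adjusted p = 0.00347), and the call was lost with an estimated correlation (adjusted p = 0.436). The members with the smallest p were Wfdc2 (780.2 ± 104.5 against 1381 ± 164.0), Wfdc15b (209.2 ± 15.5 against 447.1 ± 174.3), Tmem52b (76.5 ± 9.57 against 117.6 ± 1.30) and the potassium channel Kcnj1 (58.2 ± 19.3 against 108.2 ± 22.0). Of its members 0 passed over all genes or when adjusted over the list alone, and without wildtype replicate 2 the list had a median of -0.09 and an adjusted p of 0.536. Without wildtype replicate 1 its median was -0.38.

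The other segments of the nephron did not pass as lists. Cap mesenchyme, the nephron progenitors, had 14 of 19 members lower and a median of -0.09 (camera adjusted p = 0.0907), with Spock2, Rspo1 and Cited1 at -0.69, -0.56 and -0.79 and Hoxd11 at 0.47 on the log2 scale. Early nephron genes had a median of 0.19 (camera adjusted p = 0.64), with Pou3f3 and Lhx1 at -0.59 and -0.48 and Dkk1 and Fgf8 at 0.91 and 0.30. Podocyte genes had a median of -0.03 (camera adjusted p = 0.503), and 1 of 17 passed when adjusted over the list alone. This was Cdkn1c, a cell cycle inhibitor and imprinted gene, 4.09-fold lower (log2 difference -2.03, SE 0.38). Nphs1, Npnt and Rasl11a had log2 differences of 0.93, -0.36 and -0.39. Proximal tubule genes had a median of -0.07 (camera adjusted p = 0.0965), with Cdh6, Slc5a12, Spp2 and Amn at -0.65, -0.88, -0.60 and 0.35. Without wildtype replicate 1, the cap mesenchyme and proximal tubule lists passed, with adjusted p of 0.00207 and 1.4e-05. Without labelled Tfrc-null replicate 1 they also passed, with 0.0298 and 0.00186. Neither passed without wildtype replicate 2, where the cap mesenchyme median was -0.03 (adjusted p = 0.969) and the proximal tubule median turned to 0.19 (0.669). Nor did they without labelled Tfrc-null replicate 2, with medians of -0.01 (0.317) and 0.13 (0.97).

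Stromal and mesenchymal genes were higher as a group on the labelled Tfrc-null arrays, in 27 of 28 members with a median log2 difference of 0.44 (camera adjusted p = 6.9e-09). The call was lost with an estimated correlation (adjusted p = 0.436). Without wildtype replicate 1 the median was 0.66. Dlk1, an imprinted regulator of progenitor cells, stood at 1364 ± 253.0 against 294.1 ± 119.8, and the matrix proteoglycan Lum at 122.0 ± 12.2 against 44.2 ± 12.7. Tbx18, a transcription factor of ureteral mesenchyme, stood at 88.8 ± 31.5 against 31.3 ± 1.85, and Postn at 987.7 ± 239.6 against 343.3 ± 165.9. Dlk1, Lum and Tbx18 passed when adjusted over the list alone, and 0 members passed over all genes. Endothelial genes were lower in 21 of 22 members, with a median of -0.77 (camera adjusted p = 9.3e-12, and adjusted p = 0.436 with an estimated correlation). The median was -0.36 without wildtype replicate 1 and -0.51 without labelled Tfrc-null replicate 2, and the list passed in both cases. Sox17, a transcription factor of arterial endothelium, stood at 152.0 ± 23.4 against 433.4 ± 78.7 and the lipase-binding protein gene Gpihbp1 at 109.0 ± 7.95 against 273.3 ± 8.41. Cd93 stood at 1238 ± 45.8 against 2381 ± 136.0 and the phosphatase Ptprb at 122.9 ± 6.37 against 244.8 ± 27.2. Of the 22 members, 0 passed over all genes and 6 passed when adjusted over the list alone, all lower: these 4, Kdr and Plvap, the last 2 named after their values were seen.

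Erythroid genes were lower in 22 of 24 members, with a median of -0.58 (camera adjusted p = 1.1e-10, and adjusted p = 0.436 with an estimated correlation). The size depended on the wildtype arrays: the median was -0.20 without wildtype replicate 2 (adjusted p = 0.000201) and -0.87 without wildtype replicate 1. The anion exchanger of red cells Slc4a1 stood at 20.3 ± 8.12 against 349.9 ± 230.9. Among globins, Hbb-y stood at 26.2 ± 28.7 against 1351 ± 902.2, Hbb-b2 at 401.6 ± 200.6 against 2651 ± 1210 and Hba-x at 9.60 ± 0.790 against 154.6 ± 134.0, though probes of one globin can bind another. Over all genes 0 members passed, and 7 passed when adjusted over the list alone, all lower: these 4, Tspan33, Trim10 and Hemgn, the last 3 named after their values were seen. Genes of leukocytes and macrophages had a median of 0.18 (camera adjusted p = 0.764), with 15 of 20 higher. The median was 0.01 without wildtype replicate 1, and the test direction turned to down without labelled Tfrc-null replicate 1 (median 0.08). The chemokine gene Pf4 stood at 830.4 ± 64.9 against 397.5 ± 42.0 and passed when adjusted over the list alone, while the pan-leukocyte gene Ptprc stood at 121.8 ± 12.7 against 201.3 ± 10.6, Ctss at 587.3 ± 121.1 against 906.9 ± 20.2 and Lyz2 at 533.4 ± 102.4 against 884.4 ± 205.5. Among cells that a kidney dissection can carry along, nerve and neural crest genes had a median of -0.06, a mean of 0.0009 and a test direction of down (camera adjusted p = 0.969), with Elavl4 and Tubb3 at -1.16 and -0.46 and Ngfr and Fabp7 at 0.54 and 0.71. Adrenal and gonad genes had a median of -0.003, a mean of 0.08 and a test direction of down (camera adjusted p = 0.969), and the corticotropin receptor Mc2r (79.6 ± 0.971 against 34.8 ± 8.38) passed when adjusted over the list alone. Sox9 and Dhh had log2 differences of -0.70 and 0.36, and Nr5a1 was at least 1.39-fold lower, with both labelled Tfrc-null arrays at or below the control level. Pluripotency genes had a median of 0.12 (camera adjusted p = 0.383). Nanog, Tcl1, Dppa5a and Zfp42 had group means between 4.37 and 15.6, and 7 of the 14 members lay at or below the control level on all 4 arrays.

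**Figure D2:**
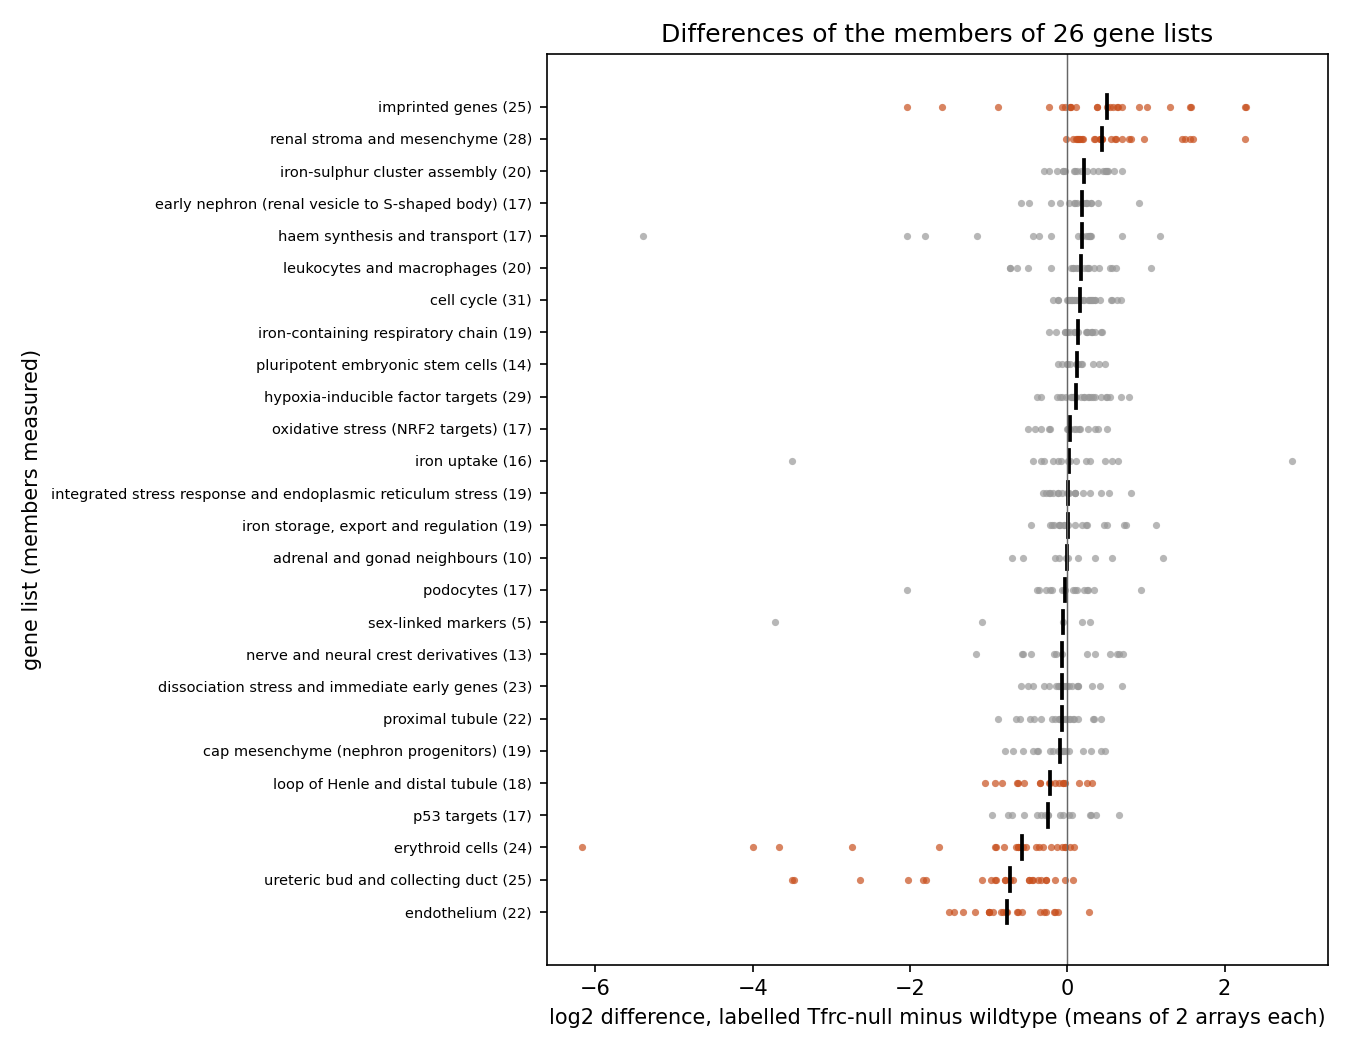
Log2 difference, labelled Tfrc-null minus wildtype (means of 2 arrays each), of every measured member of the 26 gene lists, 1 point per gene, ordered by the list median (black bar), with the 6 lists past a camera adjusted p of 0.05 in orange. The median is -0.73 for ureteric bud, -0.77 for endothelium and -0.58 for erythroid genes, against 0.44 for stroma and 0.50 for imprinted genes.

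Imprinted genes, which are expressed from the allele of one parent, were higher as a group, in 19 of 25 members with a median of 0.50 (camera adjusted p = 0.00151, and adjusted p = 0.436 with an estimated correlation). Mirg, a noncoding RNA of the Dlk1 and Meg3 locus, stood at 64.1 ± 0.522 against 21.6 ± 1.60. Asb4 stood lower, at 161.5 ± 1.60 against 485.7 ± 24.6, as did Cdkn1c. Over all genes 0 members passed. When adjusted over the list alone 11 passed, 8 higher and 3 lower: Mirg, Dlk1, Meg3, Peg10, Sgce, Impact, Magel2 and Dcn were higher, and Asb4, Cdkn1c and Grb10 lower, with those other than Mirg, Dlk1, Asb4 and Cdkn1c named after their values were seen. Dlk1 and Dcn are also in the stroma list. Of 5 sex-linked genes measured, Xist, the noncoding RNA that silences an X chromosome in female cells, stood at 31.7 ± 9.98 against 434.8 ± 224.9. The Y-linked genes Kdm5d, Eif2s3y and Uty stood at 106.7 ± 2.62 against 226.7 ± 16.1, 597.1 ± 102.5 against 490.6 ± 88.1 and 21.9 ± 0.680 against 19.7 ± 6.11. Xist and Kdm5d passed when adjusted over the list alone, and the list had a camera adjusted p of 0.0535. It passed without labelled Tfrc-null replicate 2 (0.0479), with the mean of probe sets (0.0275), the intensity trend (0.048), median centring (0.0458) and members at or above the median level (0.0382), but not in the other leave-one-out fits (0.0603 to 0.13).

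Stress and growth genes did not pass as lists. The p53 targets had a median of -0.24 (camera adjusted p = 0.0535), with Trp53inp1, Perp, Ddit4l and Plk2 at -0.70, -0.96, -0.56 and -0.75. This list passed with the low-value filter (adjusted p = 0.0484) and with members at or above the median level (0.0352). With 1 array left out it did not pass (0.0723 to 0.198), and its median was -0.065 without labelled Tfrc-null replicate 2, -0.16 without labelled Tfrc-null replicate 1 and -0.12 without wildtype replicate 1. Cell cycle genes had a median of 0.17 with 28 of 31 higher (camera adjusted p = 0.0535), among them Ttk, Tyms, Aurka and Plk1 at 0.56 to 0.68, and this list passed with the replicate block (adjusted p = 0.0202), the intensity trend (0.048) and ranks (0.0325) but not with the block and an estimated correlation (0.867). It hung on the wildtype arrays: without wildtype replicate 2 the median was -0.006 (adjusted p = 0.969), and without wildtype replicate 1 it was 0.32 (adjusted p = 0.00016). It passed without labelled Tfrc-null replicate 2 (adjusted p = 0.0355) and had a median of 0.08 without labelled Tfrc-null replicate 1 (0.254). Targets of hypoxia-inducible factors had a median of 0.12 (camera adjusted p = 0.153), with P4ha2, P4ha1, Car9 and Pfkfb4 at 0.68, 0.49, 0.79 and -0.33, and passed without labelled Tfrc-null replicate 1 (median 0.31, adjusted p = 0.000819). The test direction turned to down without labelled Tfrc-null replicate 2 (median 0.03, adjusted p = 0.701), and the median was 0.05 without wildtype replicate 1 (0.794). The integrated stress response had a median of 0.01 (camera adjusted p = 0.969), with Asns, Ddit3, Hyou1 and Sesn2 at 0.81, 0.53, 0.29 and 0.43. Oxidative stress genes had a median of 0.03 and a test direction of down (camera adjusted p = 0.969), with Gclc and Gsta3 at -0.41 and -0.50 and Gstm1 and Hmox1 at 0.36 and 0.50. Immediate early genes of dissociation stress had a median of -0.07 (camera adjusted p = 0.383), with Junb, Nr4a1, Myc and Egr2 at 0.42, -0.59, -0.29 and -0.44. They passed without labelled Tfrc-null replicate 2 (median -0.27, adjusted p = 0.000554) and turned to higher without labelled Tfrc-null replicate 1 (median 0.24, adjusted p = 0.155). In each of these 6 lists, 0 members passed when adjusted over the list alone. The number of lists past the threshold was 6 with all arrays and 10 without either labelled Tfrc-null array.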

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

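The tests of explanations in this part were chosen after the results they bear on had been seen, while quantile normalization and median centring of the lists were planned. Probe sets outside the gene-level comparison, because the annotation gives them several genes or none and leaving out Affymetrix control probe sets, carried signal on the wildtype arrays that was lower on the arrays labelled Tfrc-null. Of 10092 such probe sets, 42 were at least 2-fold higher and 206 at least 2-fold lower without overlap of the groups. The brightest several-gene probe set of alpha-globin had a log2 difference of -3.64 (1112 ± 24.3 against 14150 ± 4008), that of beta-globin -3.09 (1272 ± 95.0 against 10990 ± 2845) and that of stefin A -6.30 (39.1 ± 22.8 against 2912 ± 1108). Not every globin signal was lower by as much. The probe set used for Hba-a2 alone stood at 387.6 ± 136.5 against 414.3 ± 88.2 (log2 difference -0.13, SE 0.32).

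Tfrc was not lower in the arrays labelled Tfrc-null. Wildtype cells carried over by the sort would bring Xist along at the same share, if they held Xist as the cells on the wildtype arrays did. Whether both groups came from the same kidneys is not stated in the labels. The 2 Xist probe sets above the control level on all arrays stood at 5.81% and 7.62% of their wildtype level. Tfrc stood at 138.9%. Under that condition, these values argue against carry-over as the source of the whole signal. Exchanged labels would make the arrays labelled wildtype those of 1 donor line, yet they held Xist at 276 or more together with Eif2s3y at 428 or more, a pairing that one stem cell line is not expected to give if it was of one sex, which the labels do not state. Whether the probe sets lie outside the deleted part stays open: the 5' probe set was at or below the control level on 4 of 4 arrays, and the deleted part is not given in the sources used here. A transcript that is still made from the deleted gene is a possible explanation that these values could not separate from a wrong label.

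Erythroid genes were lower on the arrays labelled Tfrc-null (list median -0.58), and so were 13 of 19 granulocyte markers, from a list written after the values of most of them had been seen. A loss of erythroid cells alone was first tested by the median over all 19. It was -0.421, on the side of the bound of 1.5-fold that such a loss predicts. This median cannot decide, since Elane, Ctsg, Gfi1, Cxcr2 and Chil3 lay at or below the control level on both wildtype arrays. At that level a fall cannot be measured. Of the 19, 9 were lower without overlap and by over 2 SE, and 0 were higher in this way. The share of all genes lower in this way gives 1.17. The 9 include Chil3, which lay at or below the control level on every array, so its difference is not a measured drop. All 8 at or above the median level were lower, with a median of -2.28. That level was taken over the arrays of both groups, so Ngp and Ltf reached it only through their wildtype values. Such a filter favours markers with a large drop, so this median decides nothing. The count of 9 against 1.17 argues against a drop limited to erythroid genes, though this measure and the list itself came after values had been seen. No donor contribution to any blood lineage, with cells parted by GFP alone, is argued against by the leukocyte and macrophage list (median 0.179, and 0.0116 to 0.224 with 1 array left out), unless macrophages entered the GFP-positive gate by their own fluorescence, which was not measured. Host blood in the GFP-negative gate and a requirement of Tfrc for blood formation in donor cells, the difference the design names, cannot be told apart, since both would give a lower erythroid list.

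Ureteric bud genes were lower. A batch marked by the replicate number is argued against by the design, since each number holds 1 array of each group, and by the list within the numbers, with medians of -0.84 and -0.67 and upper quartiles of -0.47 and -0.35. A scale factor shared by all genes of an array is argued against as the reason why this list lay below the other genes. The median difference over all genes was 0.04, and stroma genes were higher in 27 of 28 members. A shift of all genes that RMA had removed before would not be seen. Quantile normalization and median centring moved the list median little, to -0.71 and -0.70, and so decided nothing. A smaller share of ureteric bud cells among the sorted donor cells cannot be told apart from lower expression per cell. Ret stood at 9.03% of its wildtype level but Wnt11, another gene of bud tips, at 77.2%. Etv4 and Etv5 of the same list stood at 82.8% and 79.2%. Expression of Wnt11, Etv4 or Etv5 in other kidney cells could hide a loss. An effect of Tfrc itself stays open and untested.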

How the results depend on the processing

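The combinations with the block were added after seeing the data, and the cause of the changes given here was not tested unless stated. With 0 genes past the threshold in the main test, 2 passed with the replicate block, 1 with the mean of probe sets, 2 with the intensity trend, 2 with median centring and 1 at a threshold of 0.10, and 0 with each other alternative, including every leave-one-out fit. The block with the filter gave 149 and the block with the trend 35. Same-numbered arrays deviated together (r = 0.512 across genes, which are not independent), but 2 pairs do not show that the numbers pair the samples. The genes with at least a 2-fold difference and no overlap numbered 309 with the mean of probe sets and 600 to 919 without 1 array, where fewer arrays make separation easier. Lists past the threshold numbered 6 to 10 without 1 array and 0 with the estimated correlation, with fry, and with both block and estimated correlation. The 6 lists kept their call and direction under the other alternatives, except the loop of Henle list without wildtype replicate 2. Its adjusted p was 1.4e-05 to 0.536 over the leave-one-out fits. For the erythroid, endothelium, loop of Henle, ureteric bud, stroma and imprinted lists the adjusted p was 0.436 with the estimated correlation, 0.867 with block and estimated correlation, and 0.241, 0.194, 0.394, 0.171, 0.171 and 0.171 with fry. All these fry results are of its directional test. Its mixed test, which takes differences either way, is not counted among the alternatives here. It passed for ureteric bud (adjusted p = 0.0307), stroma (0.0449), endothelium (0.0481), imprinted (0.0154) and sex-linked genes (0.0283). Iron uptake, haem, and adrenal and gonad genes passed too (0.00952 each), and erythroid (0.147) and loop of Henle genes (0.275) did not. The estimated correlation called 0 of 10 simulated shifts of the ureteric bud list by 0.5, and larger shifts or other lists were not simulated. The nerve list turned to higher without labelled Tfrc-null replicate 1 (adjusted p = 0.0478, and 0.0478 to 0.681 over the leave-one-out fits), as did Egr2 (0.0674, range -0.946 to 0.0674). With the mean of probe sets Lhx1 (0.0193) and Dhh (-0.59) turned, and Dppa5a turned without wildtype replicate 1 (-0.095, range -0.095 to 0.909). Of 1580 combinations of 134 named genes and alternatives, 1565 kept the sign. Much of this was fixed in advance. The block, the filter and the trend leave a gene's log2 difference as it is. Genes named for the absence of overlap cannot turn when 1 array is left out. The count is therefore no measure of stability. Of the 20 lists not past the threshold, 9 passed under some alternative and 10 had another test direction in a leave-one-out fit. Signal over background limits the low genes: 76.8% to 82.8% of genes lay above the control level of an array.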

Other observations

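All tests in this part were chosen after the results they bear on had been seen, except that the chromosome test itself was planned and only its bound was written afterwards. Granulocyte markers, a group outside the lists of the report, were in part lower on the arrays labelled Tfrc-null, in a list written after the values of most of them had been seen. S100a8 and S100a9, which encode the calprotectin subunits, stood at 214.4 ± 202.8 against 2937 ± 1300 and 89.7 ± 95.7 against 2812 ± 775.0 (SD, n = 2). The granule protein genes Ngp and Ltf stood at 8.41 ± 1.30 against 179.7 ± 137.9 (Ngp) and a log2 difference of -2.68 (Ltf), and Mmp9 at 20.9 ± 3.14 against 76.8 ± 2.89. Of 19 markers measured, 13 were lower, and camera passed the threshold of 0.05 with its preset correlation but not with an estimated one. None of the 22 markers is in another list here, and Lcn2, lower too, is a product of granulocytes as well as of collecting duct.

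A hypothesis on imprinted genes was that the donor line had shifted towards paternally expressed genes. The 14 paternally expressed genes measured had a mean log2 difference of 0.75 and the 9 maternally expressed genes -0.16, which differed with p = 0.0317 in a two-sided exact permutation test across genes. Genes of one imprinted cluster are not independent, which the test does not allow for, so the p is too small by an amount that was not measured. The maternally expressed Meg3 and Mirg were higher together with the paternally expressed Dlk1 of the same locus. Dlk1 and Dcn are also in the stroma list, which was higher in 27 of 28 members. The test cannot tell a shift of imprinting apart from a different mix of cells.

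A second hypothesis was that Scara5 was higher because stroma as a whole took a larger share of the sorted donor cells. The upper quartile of the stroma list was 0.79 on the log2 scale and the Scara5 difference 2.86 (SE 0.33), but stroma genes with a high baseline in other cells can hide a change in share. Dlk1, at 2.26 (SE 0.34), lay close to Scara5, but its second probe set stood at 1.04 (SE 0.18) and the gene is imprinted. A larger share therefore stays open.

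Stem cell lines can gain chromosomes in culture. Camera called 0 of 20 chromosomes (smallest camera adjusted p = 0.996). The highest chromosome median was 0.077 over all genes and 0.103 over genes at or above the median level. On the log2 scale, 3 copies in place of 2 in all cells would give about 0.58. A gain of a whole chromosome in most donor cells is argued against. A gain in few cells would not be seen.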
